A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

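The samples were 4 libraries from wild-type yeast grown to mid-log phase, 2 with Arp4-3Flag and 2 with no tag, grouped by the genotype in the labels. Per the labels, chromatin was sonicated and precipitated with an antibody against Flag. Per the submitters' processing notes, fastp 0.21.0, BWA 0.7.15-r1140, SAMtools 1.4 and MACS2 were used, with no settings stated. The genome build, the control used for peak calling, the threshold, the treatment of reads that map to several places, and whether the 2 tagged libraries were pooled are not given in the sources used here.

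The deposited data analysed here are 1 list of peaks without a header, in the layout that MACS2 writes. Positions are the deposited starts, ends and summits, given here counted from 1. The authors' fold enrichment is a linear ratio at the summit over what the peak caller took as background. The authors' −log10 values are of the caller's p and q, and the lowest −log10 q was 1.31, which corresponds to a q of 0.0493. The deposited score equals the whole-number part of 10 times the −log10 q in 100% of peaks and was not used further. Read depth is unknown, and with 1 list neither replicate agreement nor signal in the untagged cells could be measured. All p-values therefore compare places or genes within this list and measure no spread between cultures. Intervals on shares cover counting error over genes or summits only.

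Gene positions came from a table of R64 genes with no sequence. Because no build is named with the peaks, the match was checked on the peaks themselves. At the positions as given, 46 tRNA genes had a summit within 100 bp, against 1 to 10 after moving summits by 200 to 1000 bp in either direction. The median signed distance over 48 tRNA genes with a summit within 150 bp was 4.5 bp. On all 16 chromosomes the first 100 bp of genes held more summits than random placement, by 1.87 to 7.37 times. Peaks were therefore assigned to R64 genes, strand was read from the systematic names, and coordinates are printed only for peaks. A build that differs by a few bp in places would not have been noticed.

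Feature classes and locations were tested by placing peaks at random within their own chromosome 10000 times, keeping width and summit offset. The two-sided permutation p was adjusted by the Benjamini-Hochberg method over 5 classes or 4 locations, and at least 1 bp of overlap counted. Gene lists were tested by two-sided Fisher's exact tests over 6002 protein-coding genes, adjusted over 29 lists. Of 884 names in the lists, 879 matched the table. Fold enrichment was compared by two-sided permutation of the difference in medians with 100000 resamples, adjusted over 29 classes with at least 5 peaks. Odds ratios within strata of upstream length were pooled by the Mantel-Haenszel method over 5 strata. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

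The tests of feature classes, locations, promoter lists and fold by class, their gene lists and most alternatives were chosen before the data were examined. Chosen afterwards were the zones around gene starts and in ribosomal protein promoters, divergent against tandem regions, body summits and their fold classes, promoter against body fold, and summit counts in chromosome ends and tRNA genes. The class of spliceosomal and RNA polymerase III genes also holds the telomerase RNA TLC1 and the RNase MRP RNA NME1. Its members were listed after the peaks had arrived but before their result. Genes were named by a rule fixed beforehand: the 20 peaks of highest fold, up to 4 members of highest fold in each list or class described, ARP4, SWC4 and genes of their complexes, and up to 2 members with and 2 without a peak in lists below background. Examples given for a list are of this kind.

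On simulated data, 20 random peak lists gave 0 calls in 100 class tests, 0 in 580 gene list tests and 1 in 20 fold tests. These lists were drawn by the same random placement that the class tests use, so few class calls were to be expected. They cannot show errors that arise when summits gather at gene starts or over highly used genes. In 5 lists with 50 planted tRNA genes and 50 planted ribosomal protein promoters, both sets were called in 5 of 5, and a planted fold of 1.3 in 60 peaks was called in 5 of 5. Alternatives covered stricter thresholds (fold at or above the median, −log10 q of at least 10), peak width, overlap rules, promoter windows, random placement and the fold statistic. Base composition, motifs and codon usage were planned but not run, since no sequence was used here. Centromeres, replication origins, transposable elements and telomeric repeats were not analysed here, exon structure was not used, and genes of transposable elements were not removed from the gene background.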

Results

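Chromatin immunoprecipitation with sequencing was used to locate Arp4 on the chromosomes of the budding yeast Saccharomyces cerevisiae. Arp4 is a nuclear actin-related protein shared by the NuA4 histone acetyltransferase and by the SWR1 and INO80 chromatin remodelling complexes. Swc4, which the series title names together with rDNA, tDNA and telomere loci, is a subunit of NuA4 and SWR1. Wild-type cells growing exponentially in rich medium carried either Flag-tagged Arp4 (Arp4-3Flag, 2 samples) or no tag (2 samples), and both were precipitated with an antibody against Flag. The data analysed were 1 peak list with 1430 peaks on 16 nuclear chromosomes. The list has no values per sample, so no value below carries a replicate error, the read depth behind it is unknown, and signal in the untagged cells was not analysed here.

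Peaks were narrow and mostly of low enrichment. The median width was 359 bp, the range was 220 to 3036 bp, and the peaks together covered 646541 bp, or 5.36% of the genome span. Fold enrichment and q are the authors' values and are used here only to describe and rank peaks within this list. The median fold enrichment was 1.66 and the range was 1.02 to 6.32. A fold of at least 2 was reached by 346 peaks (24.2%) and a fold of at least 3 by 81 peaks. The weakest peak had a −log10 q of 1.31.

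Of the 20 strongest peaks, 13 had their summit in the promoter of a ribosomal protein gene. The highest fold, 6.32, was at FUN12, which encodes a translation initiation factor (chromosome I, 75837 to 76844), with the summit 54 bp inside the gene. RRP7, needed for ribosomal RNA processing, followed with a fold of 6.28 (chromosome III, 65316 to 65718, summit 33 bp inside the gene). A peak between the divergent genes TOA1, encoding a subunit of the general transcription factor TFIIA, and SLK19 had a fold of 6.02 (chromosome XV, 712385 to 712961). The ribosomal protein genes RPS21B (5.15) and RPL42B (5.08) came next, then UTP9 (5.06) and NHP2 (4.91), which act in ribosome assembly. The gene of the SWR1 ATPase itself ranked eighth, with a fold of 4.62 and a summit 15 bp inside the gene (chromosome IV, 1135665 to 1136290). Of the remaining 12, RPL19B, RPS24A, RPS23A, RPL11A, RPL2A, RPL6A, RPS17A, RPL23B, RPS18A, RPL16A and RPL21A had folds of 4.03 to 4.60. The twelfth was at YPR170W-B, with 4.07.

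The first comparison asked where Arp4 peaks lie relative to genes. Summits were concentrated at gene starts, on both sides of a depleted stretch just upstream. The first 200 bp inside genes held 380 summits, against 140.4 with random placement on the same chromosome (2.71-fold). The stretch from 700 to 200 bp upstream also held 380, against 192.3 (1.98-fold), whereas the 200 bp directly upstream of the start held 72 against 131 (0.549-fold). The p of each of these 3 zones was 2.0e-04 by two-sided permutation, the smallest that 10000 placements can give. The zones were drawn after the profile had been seen, and the annotated start is the reference point, since transcription start sites were not used here.

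**Figure D1:**
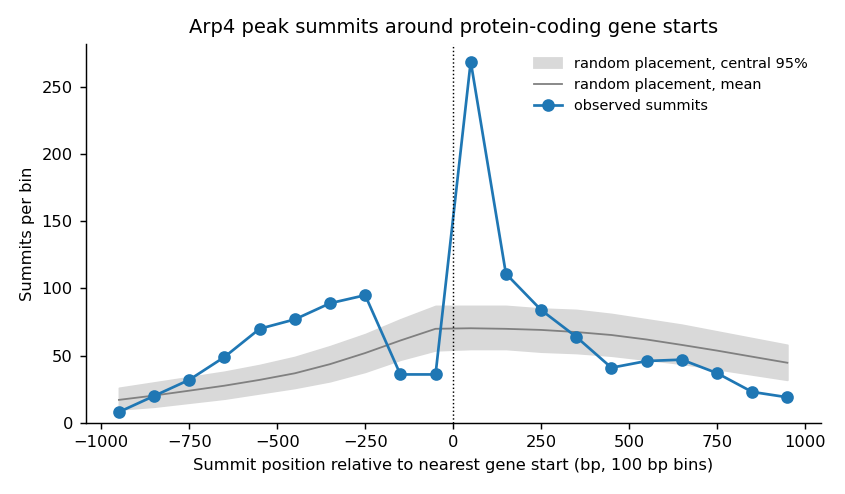
Number of Arp4 peak summits (vertical axis) by position relative to the nearest protein-coding gene start (horizontal axis, bp, 100 bp bins, positive values inside the gene). Points are the observed counts, the grey line and band the mean and central 95% of 10000 random placements; the bin of the first 100 bp inside genes holds 269 summits against 70.4 with random placement.

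By location, summits favoured divergent promoters and RNA genes and were scarce between convergent genes. RNA genes held 57 summits against 7.01 with random placement, and intergenic DNA upstream of at least 1 gene held 372 against 318 (1.17-fold). Intergenic DNA between convergent genes held 10 summits against 61.5, a ratio of 0.163. Protein-coding gene bodies held the most summits, 991 (69.3%, Wilson 95% interval 66.9 to 71.6), slightly fewer than the 1044 placed there at random. Adjusted over the 4 locations, the two-sided permutation p was 4.0e-04 for RNA genes and for convergent DNA and 0.0026 for the other two. Divergent intergenic regions held 204 summits against 124.7 (1.64-fold, adjusted permutation p = 4.0e-04), whereas tandem regions held 168 against 193.2 (adjusted permutation p = 0.051). The 500 bp upstream of gene starts held 475 summits against 304.6 (1.56-fold, permutation p = 2.0e-04).

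The second comparison took up the loci in the series title: tRNA genes, rDNA and chromosome ends. Arp4 peaks overlapped 60 of 275 tRNA genes (21.8%, Wilson 95% interval 17.3 to 27.1), against 16.8 with random placement, a 3.58-fold excess (adjusted permutation p = 5.0e-04). The tRNA genes with the highest fold were SUF8 (2.74; chromosome VIII, 388802 to 389058), YNCN0017W (2.35), YNCO0011W (2.33) and SUP17 (2.31; chromosome IX, 248778 to 249530). The summit itself lay inside a tRNA gene for 37 peaks, against 2.59 with random placement (permutation p = 2.0e-04). When random summits were kept out of protein-coding genes, the tRNA excess was 1.18-fold and did not pass (60 against 50.7, adjusted permutation p = 0.22, at most 0.001 in the 8 other alternatives). That placement moves all 1430 summits outside genes although 991 lay inside them, which by itself raises the number expected on RNA genes. Summits inside tRNA genes, a count added after that result, were still 3.87-fold more frequent than with this placement (37 against 9.57, permutation p = 2.0e-04).

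In the rDNA, which lies on chromosome XII, 6 of 8 annotated 35S and 5S genes overlapped a peak, against 1.83 with random placement (adjusted permutation p = 6.7e-04). The 5S genes RDN5-3, RDN5-4, RDN5-5 and RDN5-6 each had 1 peak with a fold of 1.55 to 2.41, highest at RDN5-4 (481971 to 482318). Their −log10 q was 47.7 to 230, against a median of 15.9 over all peaks. RDN5-1 and RDN5-2 had none. The 35S genes RDN37-1 and RDN37-2 carried 9 peaks with folds of only 1.02 to 1.24, among the lowest in the list, although the strongest of them (451830 to 452056, in the 25S gene) had a −log10 q of 217, and 2 of them barely passed (1.45 and 1.34). With random summits kept out of protein-coding genes the rDNA excess was 1.88-fold (adjusted permutation p = 0.085), and with peaks of at least the median fold it was 2.91-fold (0.12). The other 6 alternatives gave an adjusted permutation p of at most 0.0027. These genes are near-identical copies, so the 8 are not independent.

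Chromosome ends held fewer Arp4 peaks than the rest of the genome. The outermost 20 kb of 16 of the 32 chromosome arms had a peak, against 28.8 with random placement (0.556-fold, adjusted permutation p = 5.0e-04). These regions held 31 summits, against 73.0 with random placement (permutation p = 2.0e-04), and their median fold was 1.45. Peaks there reached a fold of 2.76 on the left arm of chromosome XIII and 2.31 on the right arm of chromosome VI. The subtelomeric Y' helicase genes, described below, went the other way, with summits inside 6 of 8. The silent mating loci HML and HMR overlapped no peak, and with 2 members they were not tested. Chromosome ends were taken as the outermost annotated gene or peak, and how uniquely reads map there was not tested.

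Other non-coding RNA genes did not pass the test. Among snoRNA genes 9 of 75 overlapped a peak, against 5.46 with random placement (adjusted permutation p = 0.23), with SNR4 (2.48), SNR17B (2.35), SNR32 (2.11) and SNR31 (2.03) highest. The SNR32 peak has its summit inside the ribosomal protein gene RPL42B. The class of 10 spliceosomal and RNA polymerase III genes also holds TLC1 and NME1, so it does not stand for polymerase III genes alone. Of these 10, 3 overlapped a peak. They were SCR1, the signal recognition particle RNA (1.89), RPR1, the RNase P RNA (1.71), and LSR1, a spliceosomal RNA (1.69). That count was 2.60-fold that of random placement (adjusted permutation p = 0.23). It passed when at least 50% of the gene had to be covered (5.93-fold, adjusted permutation p = 0.039, at least 0.055 in the 8 others).

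**Figure D2:**
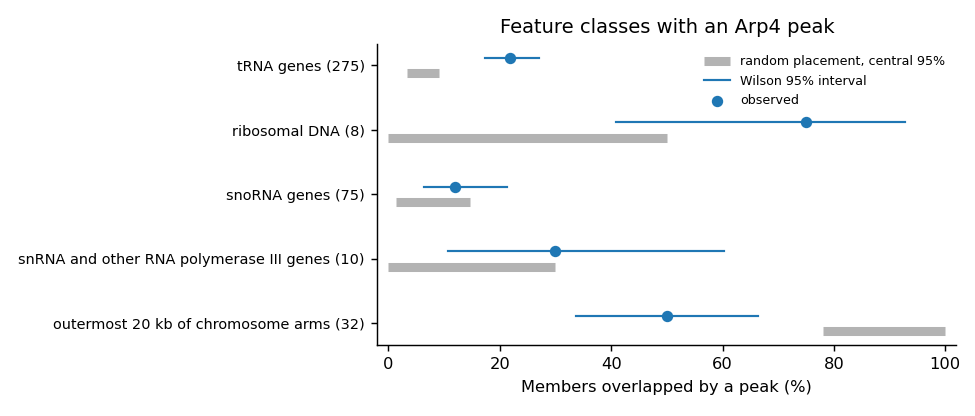
Share of members overlapped by an Arp4 peak (horizontal axis, %) for 5 feature classes, with the number of members in brackets. Points and lines are the observed share and its Wilson 95% interval, grey bars the central 95% of 10000 random placements; tRNA genes (21.8%) and rDNA (75%) lie above the bars and the outermost 20 kb of arms (50.0%) below.

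The third comparison asked which genes carried Arp4 at their promoters, taken as a summit from 500 bp upstream to 100 bp inside the annotated start. Of 6002 protein-coding genes, 839 (14.0%) had such a summit. Of 29 gene lists, 6 had more promoter summits than other genes and 1 had fewer. Ribosomal protein genes had the most such genes and the lowest p, with 76 of 137 (55.5% against 13.0% of other genes, odds ratio 8.31, 95% interval 5.89 to 11.7, adjusted p = 2.0e-29 by Fisher's exact test). Their highest folds were at RPS21B (chromosome X, 157358 to 157684), RPL42B (chromosome VIII, 382817 to 383169), RPL19B (chromosome II, 168026 to 168352) and RPS24A (chromosome V, 305934 to 306263), each with its summit 235 to 262 bp upstream of the start.

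The other lists above background also served protein synthesis, protein turnover and chromatin. Ribosome biogenesis genes had a promoter summit in 26 of 80 cases (32.5%, odds ratio 3.05, adjusted p = 3.3e-04 by Fisher's exact test), led by RRP7, UTP9 and NHP2. Mitochondrial ribosomal protein genes had one in 22 of 67 (32.8%, odds ratio 3.10, adjusted exact p = 9.9e-04), among them MRPS18 (3.71), MRPL8 (2.64) and RSM27 (2.52). Of these genes, MRPS12 and RSM19 shared 1 peak (1.79). In all lists a summit counted for every gene whose window held it, so genes were not fully independent. Translation factor genes had one in 9 of 26 (34.6%, odds ratio 3.36, adjusted exact p = 0.027), with GCD11 (3.64), NIP1 (3.27) and EFB1 (3.25) below FUN12. The proteasome list had 11 of 33 (33.3%, odds ratio 3.17, adjusted exact p = 0.018). It was led by PRE2 (4.21), whose peak is shared with the divergent gene RPL11A, and by RPN4 (3.51), the transcriptional activator of proteasome genes. Histone genes had the highest share, 6 of 10 (60%, odds ratio 8.94, adjusted exact p = 0.0068), but HTA1 and HTB1 shared 1 peak (1.93), as did HHT2 and HHF2 (1.83). The histone list no longer passed under either stricter threshold. The translation factor list no longer passed with a window reaching 1000 bp upstream, with any peak base counted, or without genes near tRNA genes or with body summits.

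Sporulation and meiosis genes were the list with fewer promoter summits, 0 of 45 (Wilson upper limit 7.87%, against 14.1% of other genes, adjusted exact p = 0.011); AMA1 and CRR1 are examples. DNA damage and recombination genes had 1 of 42, RNR2 (1.67), which did not pass the adjustment (adjusted exact p = 0.087). Seripauperins (0 of 24, adjusted exact p = 0.12), hexose transporters (0 of 16, 0.26) and COS genes (0 of 12, 0.54) did not pass either, although seripauperins passed as lower with the 1000 bp window and with any peak base counted, and DNA damage genes without summits in gene bodies. Glycolysis and fermentation genes had 2 of 19, PGK1 (2.40) and ENO1 (1.3), close to the 14.0% of other genes. With a narrower window, from 250 bp upstream to the start, the ribosomal proteins were the 1 list still higher and no list was lower. This window leaves out the first 100 bp inside genes and is mostly the depleted 200 bp upstream, so calls could be lost by its placement alone. With each summit given to its nearest start, with peaks of at least the median fold, or with a window reaching 1000 bp upstream, sporulation genes did not pass.

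Genes of the Arp4-containing complexes showed promoter summits at 5 of 14 SWR1, 4 of 13 NuA4 and 4 of 15 INO80 subunits. None of the 3 lists passed the adjustment (adjusted exact p = 0.11, 0.20 and 0.26), although SWR1 subunits did when each summit was given to its nearest start. Besides SWR1, summits lay at RVB1 (2.13), SWC7 (1.75) and BDF1 (1.59), at the NuA4 genes EAF3 (2.04) and EAF1 (1.81), and at INO80 (2.0) and IES5 (1.60). ARP4 itself had a weak peak with a fold of 1.23 and a −log10 q of 1.51, with the summit 479 bp upstream (chromosome X, 285671 to 285972). SWC4 had no summit at its promoter or in its body.

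**Figure D3:**
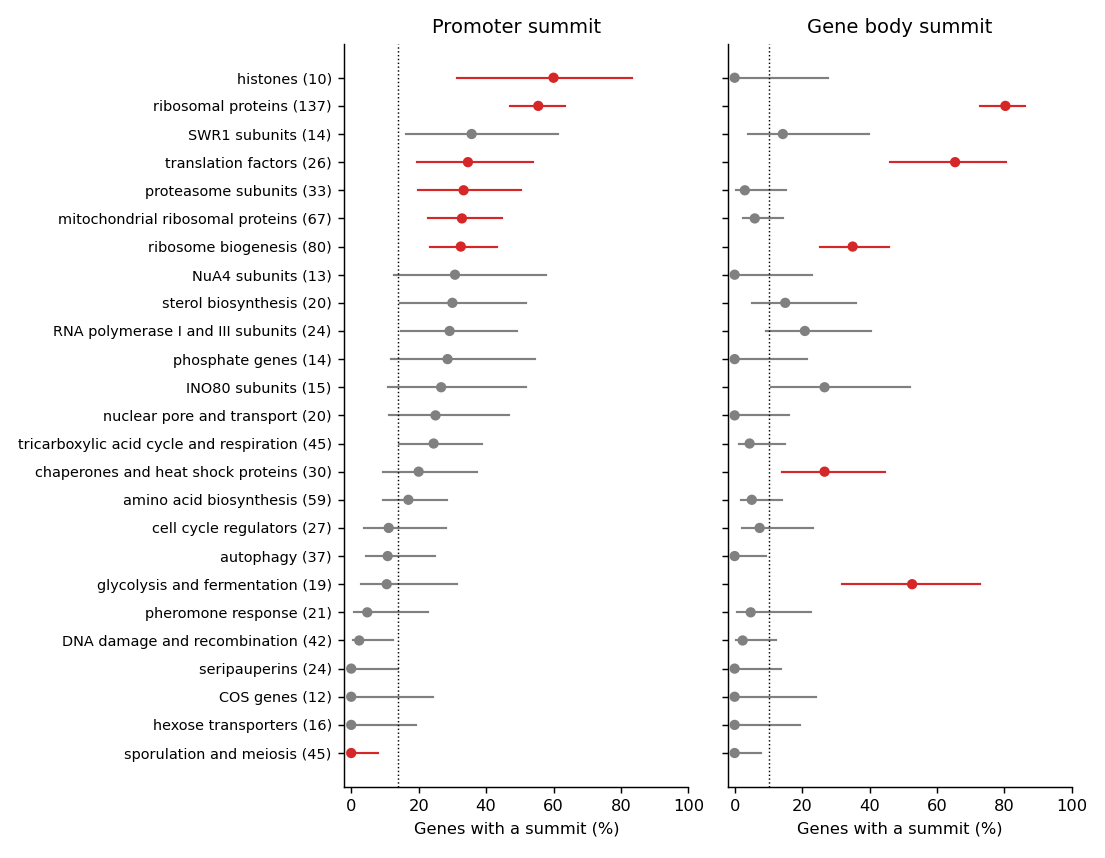
Share of genes with an Arp4 summit (horizontal axes, %) at the promoter (left) and inside the gene over 100 bp from both ends (right) for the gene lists with at least 10 measured genes, number of genes in brackets. Points and lines are the share and its Wilson 95% interval, red marks lists that passed Fisher's exact test after adjustment over 29 lists, and dotted lines mark all genes (14.0% and 10.1%); ribosomal proteins reach 55.5% at promoters and 80.3% in bodies.

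Ribosomal protein promoters also differed from others in where the summit lay. In 66 of 76 of them (86.8%) it was 400 to 150 bp upstream of the start, against 282 of 763 other genes with a promoter summit (37%, Fisher's exact p = 2.2e-17). Only 3 of the 76 had it in the first 100 bp inside the gene, against 265 of 763 (34.7%, Fisher's exact p = 6.2e-10). The median position was 243 bp upstream. By contrast, the 7 RNA polymerase I and III subunit genes with a promoter summit, led by RPC19 (3.43), RPC37 (3.03), RPC82 (2.70) and RPC10 (2.45), all had it within 100 bp inside the gene. The 2 zones were chosen after the positions had been seen.

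A further comparison, added after the files had been examined, counted summits inside genes, over 100 bp from both ends. Such summits made up 671 of the 1430 (46.9%) and fell in 609 genes (10.1%). Ribosomal protein genes had the highest share, 110 of 137 (80.3% against 8.51% of other genes, odds ratio 43.2, adjusted p = 2.9e-85 by Fisher's exact test). Among them the highest body folds were at RPL30 (2.63; chromosome VII, 439364 to 439644), RPS22B (2.54), RPL31A (2.49) and RPL40A (2.43). Translation factor genes had 17 of 26 (adjusted exact p = 2.0e-10), including PRT1 (2.56) and the elongation factor genes YEF3 (2.21), TEF1 (1.82) and TEF2 (1.81). Glycolysis and fermentation genes had 10 of 19 (adjusted exact p = 3.1e-05), including ENO2 (1.80), PDC1 (1.65), GPM1 (1.61) and CDC19 (1.55). Ribosome biogenesis genes had 28 of 80 (adjusted exact p = 1.4e-08), with NSR1 (3.09), DBP2 (3.05), BMS1 (2.63) and CBF5 (2.08) highest. Chaperone genes had 8 of 30 (adjusted exact p = 0.040), with HSC82 (2.04), YDJ1 (1.90), SSB2 (1.84) and SSB1 (1.71) highest.

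The subtelomeric Y' helicase genes had body summits in 6 of 8 (adjusted exact p = 1.4e-04), with YRF1-2 (1.51) highest, but these genes are near-identical copies and not independent. With peaks of at least the median fold, the glycolysis, chaperone and Y' helicase lists no longer passed, and the chaperone list also failed when any peak base over the body counted. Mitochondrial ribosomal proteins (4 of 67), proteasome genes (1 of 33) and histones (0 of 10), all above background at promoters, did not have more body summits than other genes (adjusted exact p = 0.54, 0.53 and 0.75).

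Promoter peaks were stronger than body peaks of the same gene. Among 132 genes with both, the promoter peak had the higher fold in 112, with a mean log2 difference of 0.59 (SD 0.53 across genes, permutation p = 1.0e-05). In ribosomal protein genes, which were 60 of the 132, it was higher in 59 of 60, with a mean log2 difference of 0.86 (SD 0.38, permutation p = 1.0e-05). This p is the smallest that 100000 resamples can give, and genes are not independent replicates.

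The last comparison set the fold of each class of peaks against all other peaks, and 11 of 29 classes were higher and 3 lower. Ribosomal protein promoter peaks stood highest, with a median of 3.37 against 1.64 (adjusted permutation p = 5.8e-05). Promoter peaks of RNA polymerase I and III subunits (2.45, adjusted permutation p = 0.0093), translation factors (2.27, 0.0093), proteasome genes (2.22, 0.0080), ribosome biogenesis (1.98, 0.0080) and mitochondrial ribosomal proteins (1.95, 0.017) were also higher. Peaks in tRNA genes had a median of 1.83 (adjusted permutation p = 0.017) and body peaks of ribosomal proteins 1.77 (0.019). The other 3 higher classes were positions around gene starts, namely summits within 500 bp upstream (1.88), intergenic upstream summits (1.81) and the first 200 bp inside genes. The upstream classes include ribosomal protein promoter peaks. Without peaks at ribosomal protein, tRNA and rDNA genes, the median within 500 bp upstream was 1.73 (240 peaks). In the first 200 bp inside genes it was then 1.82 (355 peaks), and neither was tested. rDNA peaks (1.10, adjusted permutation p = 0.0059), the outermost 20 kb (1.45, 0.035) and gene bodies (1.61, 5.8e-05) were lower. With peaks of at least the median fold, 4 classes were higher and 1 lower. The tRNA and ribosomal protein body results did not pass with means of log2 fold or with either stricter threshold, nor the outermost 20 kb with the latter. Mitochondrial ribosomal protein promoters did not pass with means of log2 fold or with the median fold.

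**Figure D4:**
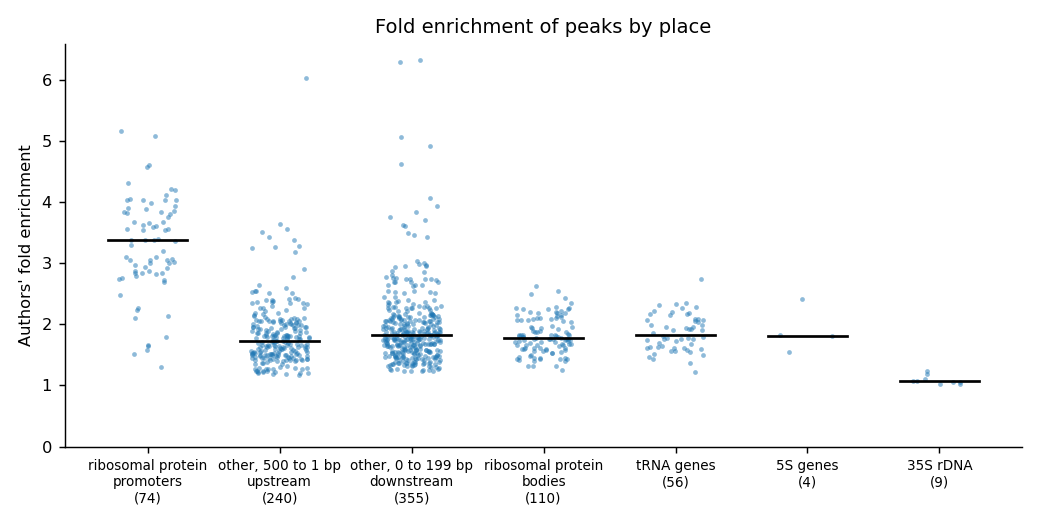
Authors' fold enrichment (vertical axis) of single Arp4 peaks by place, with the number of peaks in brackets; horizontal bars are medians and sideways scatter has no meaning. Ribosomal protein promoter peaks have a median of 3.37 and ribosomal protein body peaks of 1.77, whereas the 9 peaks in 35S rDNA lie between 1.02 and 1.24.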

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

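The circular placement, the alternatives on body summits, the removal of genes with body summits or of summits in bodies, and tRNA summits with placement outside genes were chosen after the data had been seen. No paired analysis was possible because the 1 peak list holds no values per sample, and no replicate could be left out for the same reason. Alternatives on base composition, motifs and codon usage were not run. Of 604 alternative values, 489 kept direction and side of the threshold, or as counts stayed within 1.5 times. A call was lost by 31 and gained by 12, 11 counts moved, and 61 turned direction, 5 of them from a result past the threshold and 56 with neither value past it. Some of the 56 are odds ratios above 1 in lists with 0 genes hit, named below. These come only from a small constant added to every count, so the share of genes did not turn. Upstream summits stayed 1.56-fold to 2.07-fold enriched, ribosomal protein promoters at odds ratios of 8.31 to 26.5, and the chromosome ends at ratios of 0.226 to 0.601. Requiring at least the median fold left 715 peaks. It gave rDNA a ratio of 2.91, 0 promoter lists lower, 3 body lists higher, and 4 fold classes higher and 1 lower. It also turned the fold difference of the outermost 20 kb to 0.0703 and of ribosomal protein bodies to -0.101, the latter also -0.0497 with a −log10 q of at least 10. Placement outside genes gave ratios of 1.18 for tRNA genes and 1.88 for rDNA, since it puts all summits outside genes, so that more fall on RNA genes by construction. Requiring 50% coverage gave 5.93 for spliceosomal and polymerase III genes. The 250 bp window left 1 promoter list higher and 0 lower, and turned the odds ratios of ribosome biogenesis to 0.267 and of proteasome genes to 0.648, with 0 genes hit in either. It leaves out the first 100 bp inside genes, where 13 of 26 ribosome biogenesis and 7 of 11 proteasome genes had their promoter summit. The other summits of both lists lay more than 250 bp upstream, so their loss follows from the window itself. Promoter lists lower numbered 2 with any peak base, 0 with the nearest start and 2 without summits in bodies, and body lists lower 1 with any peak base. Chaperone bodies lost their call with the median fold and with any peak base. Histones lost their call under both stricter thresholds. Translation factors lost theirs with the 1000 bp window, with any peak base, and without genes near tRNA genes or with body summits. Where no reason is given, the cause was not tested. Unknown depth limits what an absent peak means.

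In the following 56 values the estimate turned direction with no call on either side. Where a ratio above 1 is given with 0 genes hit, the share stayed below that of other genes. Placement outside genes turned the ratio of snoRNA genes to 0.588 and of spliceosomal and polymerase III genes to 0.904. The median fold turned tandem regions to 1.04. It turned promoter odds ratios to 0.737 for amino acid, 0.479 for galactose, 0.314 for phosphate, 0.535 for Y' helicase and 1.23 for autophagy genes. A −log10 q of at least 10 gave 0.412 for galactose, 0.871 for phosphate, 0.461 for Y' helicase and 1.05 for autophagy genes. The 250 bp window gave 0.887 for polymerase subunits, 0.712 for chaperones, 0.363 for amino acid, 0.476 for respiration and 1.79 for autophagy genes. Its ratios above 1 with 0 genes hit were 1.11 for glycolysis, 1.01 for pheromone, 2.90 for a-specific, 3.96 for alpha-specific, 1.74 for COS and 1.32 for hexose transporter genes. The 1000 bp window gave 1.93 for glycolysis, 0.566 for galactose, 1.4 for cell cycle and 1.46 for a-specific genes. Any peak base gave 1.02 for glycolysis, 0.622 for galactose and 0.705 for Y' helicase genes, and the nearest start 1.29 for glycolysis and 1.21 for autophagy. Without genes with body summits, glycolysis stood at 1.17 and cell cycle genes at 1.03. For body summits the median fold gave 0.682 for sterol genes. Its body ratios above 1 with 0 genes hit were 1.33 for histones, 1.48 for galactose, 1.87 for a-specific, 2.55 for alpha-specific, 1.04 for NuA4 and 1.12 for COS genes. A −log10 q of at least 10 gave 1.04 for a-specific and 1.41 for alpha-specific genes, also with 0 genes hit. Any peak base gave 1.81 for mitochondrial ribosomal proteins, 1.42 for histones, 2.16 for proteasome, 1.05 for NuA4 and 1.71 for nuclear pore genes. Fold differences of promoter peaks turned with mean log2 fold to 0.025 for amino acid and -0.0185 for respiration genes. With the median fold they turned to -0.0368 for respiration and -0.201 for sterol promoters and to -0.119 for ribosome biogenesis and -0.0568 for polymerase subunit bodies. With a −log10 q of at least 10 they were -0.0864 for respiration and -0.0635 for sterol promoters. The cause was not tested.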

Other observations

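The widest peaks, density by chromosome and the tests of body signal in the mitochondrial ribosomal protein, histone and proteasome lists and of rDNA copies were chosen after the results had been seen; upstream length and body signal were set out before the list results but after a first look at the profile.

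Several of the widest peaks lay over gene bodies. There were 18 peaks wider than 1500 bp, and these genes were named after their values were seen. The widest, 3036 bp, lay in YEF3, a translation elongation factor gene (chromosome XII, 636838 to 639873, fold 2.21). Others lay in EFT2 (2422 bp, fold 1.64), the chaperone genes SSB2 (2077 bp) and SSB1 (1749 bp), PMA1, the plasma membrane proton pump (1999 bp, 1.54), and the fatty acid synthase gene FAS1 (1557 bp). The high-affinity iron uptake gene FET3 carried one of 1835 bp (1.78). A peak of 2798 bp (2.35) had its summit 21 bp inside SEC62, of protein translocation, and 336 bp upstream of the ribosome biogenesis gene NOG1. Peak density ranged from 7.42 per 100 kb on chromosome VI to 15.1 on chromosome V, with 14.6 on chromosome XII.

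Some lists with many promoter summits also had many summits inside the gene. Ribosomal protein, glycolysis and translation factor genes, taken as highly used although usage was not measured here, had body summits in 137 of 182 (odds ratio 34.2, 95% interval 24.1 to 48.4). A general signal over such genes may therefore contribute to the ribosomal protein and translation factor peaks, although glycolysis genes had a promoter summit in only 2 of 19. Among ribosomal protein genes without a body summit, 16 of 27 had a promoter summit (odds ratio 9.70, 95% interval 4.55 to 20.7). A missing body summit does not show missing body signal. The promoter peak of RPL11A, for example, was 1064 bp wide and reached into the gene (chromosome XVI, 731133 to 732196). Very short genes could not hold a body summit at all. These 27 genes therefore cannot separate a promoter signal from a general one over the gene. The same signal stays open for ribosome biogenesis genes, which also had body summits in 28 of 80 (odds ratio 4.99, 3.1 to 7.9). Mitochondrial ribosomal protein, histone and proteasome genes had body summits in 5 of 110 (odds ratio 0.456, 95% interval 0.193 to 1.08). Their promoter odds ratio was 3.51 (2.37 to 5.22), so the promoter excess was not matched by an excess of body summits. This cannot decide against a signal spread over the whole gene. The body interval holds 1, and the lists were picked after their results had been seen. With any peak base counted, the body odds ratios also turned to 1.81 for mitochondrial ribosomal proteins and 2.16 for proteasome genes without passing the test. A signal limited to promoters was not tested, and no biological explanation was tested.

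Ribosomal protein and histone genes have longer upstream regions than other genes (medians 635 and 688.5 bp, against 444 and 449 bp), which could catch more summits. The other 4 lists called higher have shorter ones, so a longer upstream region does not account for their summits. Their medians were 313 bp for mitochondrial ribosomal proteins, 343 bp for ribosome biogenesis, 384 bp for proteasome and 388.5 bp for translation factor genes, against 449 to 451.5 bp. Within 5 strata of upstream length the lists called higher kept an odds ratio of 5.23 (95% interval 4.17 to 6.57), against 5.32 without strata. Upstream length is thus excluded as the whole cause of the pooled excess. For ribosomal proteins the odds ratio was 8.57 within strata against 8.31 without, so strata of length did not lower it. It fell from 8.94 to 7.49 for histones and from 3.36 to 2.90 for translation factors. Both kept 95% intervals above 1 (2.03 to 27.6 and 1.29 to 6.54). Length stays open as a part of the cause for histones. Translation factor genes have shorter upstream regions, so a longer region does not explain their fall, and its cause was not tested. Ratios of single lists without strata include the small constant added to every count, so small differences from the stratified ones carry little weight. No biological explanation was tested.

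The 35S peaks had some of the lowest folds in the list, and most of the 9 had a low q. Their median −log10 q of 27.8 was 15.3 times the 1.82 of 56 other peaks of no higher fold, although 2 of them, with 1.45 and 1.34, barely passed the threshold. A candidate explanation is that reads of many rDNA copies collapse on the few copies in the reference, so that depth makes small differences pass. The 5S peaks, with a median fold of 1.81, had a median −log10 q of 128. Over all peaks these medians were 1.66 and 15.9. The 5S peaks lay from 472368 to 489445 on chromosome XII, beyond the last 35S peak, which ended at 466083. RDN5-1 and RDN5-2, listed next to the 35S genes, had no peak. Collapsed copies were not tested for the 5S peaks and stay only a candidate there. The treatment of reads that map to several places is not given in the sources used here, and no biological explanation was tested.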
